A study of Mus musculus with 16 samples.

How the data were processed

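Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of endosteal mesenchymal stromal cells was compared between Bap1 WT and Bap1 cKO mice for 4 histone marks, with 2 libraries in each of 8 groups. Per the labels' protocols, cells were fixed with formaldehyde, sonicated, precipitated with antibodies against ubiquitylated H2AK119, trimethylated H3K27, acetylated H3K27 and trimethylated H3K4, and made into TruSeq libraries. Groups and replicate numbers were taken from the titles, because the antibody fields of the libraries titled H3K4me3 and H3K27ac name each other's antibody; the contrast of cKO with WT is the same either way. Input libraries were not used here, and the sex of the animals is not given in the sources used here.

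The authors deposited whole-number read counts, per the file headers, in 785000 bins of 50 bp, 200 bins over 10 kb around the start of each of 3925 genes, not normalised. The submitters' processing notes name cutadapt 1.18, Bowtie2 2.4.5, Picard 2.25.5, SAMtools 1.9, bedtools 2.30.0 and GRCm38, without settings. Each gene carries the mark UP (1904) or DOWN (2021); its contrast and threshold are not given in the sources used here. Runs of filled bins with empty bins around them were 3 bins long in 98.32% of those under 6 bins, so a read was counted in 3 neighbouring bins, and summed bins hold each read about 3 times. The read totals behind the libraries, counted once from 1 bin in 3, were 429780 to 3371280, and they cover only these windows, not whole libraries. Scaling is therefore relative to the windows measured, and a shift common to all of them is not detectable.

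Gene symbols were assigned by position, from the RefSeq annotation of GRCm38.p6: a gene on the window's strand whose 5′ end lay within 500 bp of the window's centre. This named 3019 genes (76.9%); 857 had no such gene, 25 had several and 24 repeated a name, and these keep their identifier. At positions shifted by 20 kb, 147 windows (3.75%) found a name. The central 4 kb of 302 genes overlaps that of another gene, so that their reads cannot be told apart. Coordinates are 1-based.

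For each mark, counts of the bins within 2 kb of the gene start were summed as promoter counts and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, glmQLFit with robust dispersion) on the 4 libraries of the mark, with genotype as the term. Library sizes were the sums over autosomal bins, scaled by TMM factors from autosomal 10 kb windows. Promoters were kept by filterByExpr with a minimum count of 10, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. "Rose", "fell", "higher", "lower", "gained" and "lost" refer to calls of this test. Values are given as CPM of the deposited counts, as mean ± SD of 2 libraries, and log2 changes of cKO over WT ± SE from the fit. Summing bins triples the counts but also their spread, which the quasi-likelihood dispersion estimates; testing 1 bin in 3 changed no count of calls by more than 1.5 times. The same test was made on whole autosomal 10 kb windows.

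Gene lists for the niche, the skeletal lineages, Polycomb targets and machinery, signalling, the cell cycle, housekeeping genes and other cell types were written before the data were examined, together with the design, the alternatives and the rule for named genes. That rule takes, for each mark, the 8 promoters of lowest p in each direction whose cKO libraries both lie on one side of both WT libraries, leaving out predicted, clone and receptor names, the 4 members of lowest p of each list, and Bap1, Cxcl12, Kitl, Il7, Runx2, Sp7, Pparg and Sox9, of which Bap1, Il7, Runx2 and Sp7 were not analysed here. Of the promoters this rule takes for H3K27ac, 1 is not reported here. Other genes named beside a count or an exchange of marks were chosen after their values were seen. Lists with at least 5 measured genes were tested with camera (limma 3.58.1, correlation 0.01, BH over 11 lists and 4 marks), again with an estimated correlation, and with fry. The fry test of either direction, which does not compare a list with other genes, gave adjusted p from 0.00207 to 0.183. The comparison of genes marked UP with those marked DOWN was added after the data were seen. Promoter classes are the top 10% of WT CPM in H3K27me3 and H3K4me3. Promoter shares were compared by exact permutation. Correlations between marks are across genes.

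Alternatives were total counts without TMM factors, TMM factors from promoters or from the top 10% of windows, DESeq2 1.42.0, no filter, promoters reaching 1 kb or 5 kb to each side, windows of 5 kb, each library left out in turn, the replicate number as a block, all 16 libraries in 1 fit, the top 5% for classes, and promoters above the median CPM of both marks for correlations. Alternatives chosen after seeing the data were 1 bin in 3, scaling on the outer 1 kb flanks, leaving out shared windows or the X chromosome, and a regional offset, in which each gene's change was taken relative to the median change of its 20 nearest other genes in the other Polycomb mark, or in both for the active marks ("relative to neighbouring genes"). With 1 library left out, the lone library of its group is assumed to vary like the others.

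The tests were checked on simulated counts with 200 changed genes per mark. At a fold of 2 the test recovered 84% of 50 genes for H2AK119ub1, 48% for H3K27me3, 94% for H3K4me3 and 62% for H3K27ac, and at a fold of 4 it recovered 96, 98, 100 and 100%. Smaller changes were mostly missed outside H3K4me3, with 28, 6, 70 and 28% recovered at 1.5-fold and 0, 0, 32 and 6% at 1.25-fold. False calls were 2.80, 8.43, 1.99 and 1.01% of calls. These counts held no regional shift, had the same spread for promoters of like mean count, and were scaled by known factors. In the data far more promoters were called, 1580 higher and 1240 lower of 3905 in H3K4me3. The rates are thus those of an easier case than the data. In simulated H2AK119ub1 counts with a shift of each whole chromosome, 1076 unchanged genes were called without the regional offset and 12 with it. Of 200 changed genes, 146 and 173 were recovered. The simulated shifts were equal in both Polycomb marks, and no single gene changed in H3K27me3. The measured shifts broke within chromosomes and differed between marks, so this was an easier case than the data. Figures were drawn with matplotlib 3.10.9.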

Results

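BAP1 is the deubiquitinase that removes ubiquitin from histone H2A (H2AK119ub1), a mark placed by Polycomb repressive complexes. The series asked how its loss changes histone marks in the mesenchymal stromal cells (MSCs) of the endosteum, the inner bone surface that borders the marrow and forms part of the niche of blood-forming cells. Endosteal MSCs came from C57BL/6J control mice (Bap1fl/fl, WT) and from mice whose Bap1 was deleted by Prx1-cre, a recombinase active in limb mesenchyme (cKO). ChIP-seq was done for H2AK119ub1 and H3K27me3, both Polycomb marks, and for H3K4me3 and H3K27ac, marks of active promoters. There were 2 libraries per genotype and mark, 16 in all. The labels do not say that the 2 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. For the libraries titled H3K4me3 the antibody field names anti-acetyl-H3K27, and for those titled H3K27ac it names anti-trimethyl-H3K4; both are named here by title. The WT libraries titled H3K4me3 held 58.8% ± 0.584 (SD, n = 2) of their counts within 1 kb of the gene starts and those titled H3K27ac 44.0% ± 0.840. The data cover 10 kb around the start of 3925 genes, of which 1904 carried the authors' mark UP and 2021 the mark DOWN. The contrast behind these marks is not given in the sources used here. The Bap1 locus was not analysed here, so the genotype labels have no check of their own.

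Summed over all bins, the H2AK119ub1 libraries held 2165089 and 2096676 counts in WT and 2375135 and 2881514 in cKO. The H3K27me3 libraries held 1283020 and 1334508 in WT and 1618477 and 1456334 in cKO. The H3K4me3 libraries held 6133611 and 7680117 in WT and 6719130 and 10101047 in cKO, and the H3K27ac libraries 3011826 and 3852711 in WT and 3951507 and 3680062 in cKO. The median count per promoter, the 4 kb around a gene start, ran from 95 in H3K27me3 WT replicate 1 to 1837 in H3K4me3 cKO replicate 2. Libraries of one group differed beyond sampling noise (chi-square per degree of freedom 2.00 to 3.60), and their log CPM correlated across promoters at Pearson r 0.853 to 0.990. The share of counts within 2 kb of the gene starts was 42.5% ± 1.28 (SD, n = 2) in WT and 43.3% ± 0.596 in cKO for H2AK119ub1, and 43.5% ± 0.701 and 42.7% ± 0.718 for H3K27me3 (exact permutation p = 0.667 for each). For H3K4me3 it was 78.4% ± 0.0646 in WT and 82.5% ± 0.366 in cKO, and for H3K27ac 63.1% ± 0.408 and 66.0% ± 0.897 (exact permutation p = 0.333 for each, two-sided, the smallest that 2 against 2 libraries allow).

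In cKO cells H2AK119ub1 rose at some promoters and fell at others. It rose most clearly at Hrct1 (48.3 ± 18.8 CPM in WT and 192 ± 17.4 in cKO, mean ± SD, n = 2), Wincr1, a long noncoding RNA, Trim32, an E3 ubiquitin ligase, Spty2d1, whose window overlaps that of another gene, Ctps, the CTP synthase gene, Plekhm1, Rundc1 and Nfe2l1, a stress-response transcription factor. It fell most clearly at Cdyl2 (185 ± 2.78 and 35.1 ± 24.2 CPM), Tafa5, Nphp4, a ciliary gene, Daam2, a formin of Wnt signalling, Ctnnd2, Pdzrn4 and the X-linked Jpx and Gpr173. Among 3889 promoters tested, 651 were higher and 636 lower in cKO (edgeR quasi-likelihood, BH-adjusted p at or under 0.05). The log2 change was 1.99 ± 0.23 (SE) at Hrct1 (ENSMUSG00000071001, chromosome 4, 43725188 to 43729187, adjusted p = 1.9e-14) and 2.00 ± 0.29 at Wincr1. It was -2.38 ± 0.24 at Cdyl2 (ENSMUSG00000031758, chromosome 8, 116730992 to 116734991, adjusted p = 3.5e-19), -2.58 ± 0.29 at Tafa5 and -2.76 ± 0.34 at Nphp4. H2AK119ub1 at the niche genes Cxcl12, a chemokine that holds blood stem cells in the marrow, and Kitl, the stem cell factor gene, and at Pparg, the adipocyte master regulator, did not pass the test (log2 -0.47, 0.14 and -0.37). At Sox9, the chondrocyte regulator, it rose by 0.49 ± 0.20 (adjusted p = 0.0478). Taken relative to the 20 nearest genes in H3K27me3, 247 promoters were higher and 215 lower, 150 and 172 of them among the first calls. Jpx, Gpr173, Nfe2l1 and Sox9 were no longer called, among 22 of the 51 called named genes. Hrct1 lies at 40 to 60 Mb of chromosome 4, where the outer 1 kb flanks of the windows changed by a log2 of 0.55. The log2 changes printed for Hrct1 and the other genes above include any such regional part. Without cKO replicate 1 the counts past the threshold were 4 higher and 19 lower promoters, with 41 of the 51 named calls lost, and 120 and 121 without cKO replicate 2, with 25 lost.

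H3K27me3 fell at some promoters and rose at others. It fell at Foxd1, a kidney stroma and neural transcription factor (808 ± 81.2 CPM in WT and 97.6 ± 1.87 in cKO, mean ± SD, n = 2), Phf19, an accessory subunit of the methyltransferase complex itself (517 ± 24.0 and 63.2 ± 5.92), Eya2, Prdm16, the brown fat regulator, Thpo, the thrombopoietin gene, Card10, Sema3f and Spry1, a receptor tyrosine kinase antagonist. It rose at Hoxc13 (97.8 ± 28.7 and 603 ± 48.8 CPM), Tmub1, Arid3b, Sytl2, Plcd3, Rab3b, Parm1 and Pak1. It also rose at Pparg and at Kitl (103 ± 44.0 and 283 ± 59.8 CPM). Among 3883 promoters, 483 were higher and 604 lower. Of 132 X-linked promoters among them, 91 were lower and 1 higher. Without the X chromosome 475 promoters were higher and 507 lower. The log2 change was -3.05 ± 0.27 (SE) at Foxd1 (ENSMUSG00000078302, chromosome 13, 98352242 to 98356241, adjusted p = 3.1e-25), -3.03 ± 0.28 at Phf19 (ENSMUSG00000026873, chromosome 2, 34911977 to 34915976), -3.21 ± 0.32 at Prdm16, and -2.65 ± 0.27 at Thpo, whose window overlaps that of another gene. It was 2.62 ± 0.28 at Hoxc13 (ENSMUSG00000001655, chromosome 15, 102919103 to 102923102, adjusted p = 6.3e-19), 1.94 ± 0.29 at Pparg and 1.46 ± 0.28 at Kitl. Cxcl12 (-0.33) and Sox9 (-0.04) did not pass the test. Relative to neighbouring genes in H2AK119ub1, 381 promoters were higher and 441 lower, 297 and 378 of them among the first calls. Without cKO replicate 1 the counts were 268 and 358, and without cKO replicate 2 they were 301 and 380.

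H3K4me3 changed at most of the promoters tested. The gains of lowest p included the transcription factor genes Gsc (41.5 ± 4.27 CPM in WT and 699.7 ± 25.2 in cKO, mean ± SD, n = 2), Irx1 (20.1 ± 1.79 and 539 ± 30.1) and Pax8 (22.3 ± 4.50 and 520.4 ± 11.4), together with Dio3, a thyroid hormone deiodinase, Ror2, a Wnt receptor, Hdgfl3, Kctd15 and Fbn2, a fibrillin. It fell at Col6a3, a chain of type VI collagen (409 ± 27.2 and 20.1 ± 2.17 CPM), Col1a2, a chain of type I collagen (412 ± 44.0 and 36.5 ± 5.94), Emilin1, Pparg (414 ± 16.6 and 57.5 ± 2.36), Fabp4 and Plin4, and at Hoxc13, Cdyl2, Ift27, a ciliary transport gene, and Sema5a and Snhg18, which share a window. Among 3905 promoters, 1580 were higher and 1240 lower. The log2 change was 4.07 ± 0.10 (SE) at Gsc (ENSMUSG00000021095, chromosome 12, 104471331 to 104475330, adjusted p = 1.2e-316), 4.74 ± 0.12 at Irx1, 4.56 ± 0.12 at Pax8, and 5.46 ± 0.15 at Dio3, whose window overlaps that of another gene. It was -4.33 ± 0.13 at Col6a3 (ENSMUSG00000048126, chromosome 1, 90841972 to 90845971, adjusted p = 8.4e-233), -3.51 ± 0.12 at Col1a2 and -2.84 ± 0.11 at Pparg. It was -0.75 ± 0.08 at Cxcl12 (ENSMUSG00000061353, chromosome 6, 117166574 to 117170573), -0.37 ± 0.08 at Kitl (ENSMUSG00000019966, chromosome 10, 100013630 to 100017629) and 0.88 ± 0.07 at Sox9, each past the threshold.

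H3K27ac also changed in both directions. It rose at Kctd15 (22.2 ± 2.07 CPM in WT and 412 ± 23.8 in cKO, mean ± SD, n = 2), Foxd1 (25.4 ± 2.49 and 344 ± 4.05), Irx1, Dio3, Vit, Cd24a, Slc16a6 and Epha7, an ephrin receptor. It fell at Col1a2 (567 ± 1.08 and 58.9 ± 11.9 CPM), Ccn4, a matricellular Wnt target, Srgap3, Snhg18, Cela1, St6galnac6 and Zfhx4. Among 3892 promoters, 1203 were higher and 1133 lower. The log2 change was 4.21 ± 0.19 (SE) at Kctd15 (ENSMUSG00000030499, chromosome 7, 34653510 to 34657509, adjusted p = 3.4e-18) and 3.76 ± 0.19 at Foxd1. It was -3.27 ± 0.17 at Col1a2 (ENSMUSG00000029661, chromosome 6, 4503493 to 4507492, adjusted p = 4.7e-17) and -2.37 ± 0.19 at Pparg (ENSMUSG00000000440, chromosome 6, 115358951 to 115362950). The change was -1.01 ± 0.19 at Cxcl12, -0.56 ± 0.18 at Kitl and 0.77 ± 0.15 at Sox9, each past the threshold. The change at Sox9 did not pass relative to neighbouring genes. Without WT replicate 1 the count of lower promoters was 753.

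Most of the active-mark changes followed the authors' own division of the genes. Of 1892 promoters marked UP, 1402 rose and 68 fell in H3K4me3 (median log2 0.70). Of 2013 marked DOWN, 178 rose and 1172 fell (median -0.38). In H3K27ac, 1139 rose and 66 fell of 1884 marked UP (median 0.67), and 64 rose and 1067 fell of 2008 marked DOWN (median -0.50). H3K27me3 went the other way: 157 rose and 455 fell of 1881 marked UP, with Foxd1, Phf19, Prdm16 and Thpo among the latter. Of those marked DOWN, 326 rose and 149 fell of 2002, with Hoxc13, Pparg and Kitl among the former. H2AK119ub1 rose at 459 and fell at 308 of 1887 promoters marked UP, and rose at 192 and fell at 328 of 2002 marked DOWN. Against the genes marked DOWN, those marked UP were shifted up in H3K4me3 (camera adjusted p = 9.5e-81) and H3K27ac (4.0e-89), down in H3K27me3 (0.000381) and up in H2AK119ub1 (0.0119). With an estimated correlation the adjusted p was 0.0152 for each active mark, 0.111 for H3K27me3 and 0.201 for H2AK119ub1. Relative to neighbouring genes the H2AK119ub1 shift turned down (camera adjusted p = 0.0493 with the preset correlation, and no correlation was estimated). Of those marked UP 94 were higher and 116 lower, and of those marked DOWN 153 and 99. On this scale the H3K4me3 medians were 0.43 and -0.20, with 1244 higher and 40 lower of those marked UP and 239 and 839 of those marked DOWN. The counts were 958 and 50, and 112 and 836, in H3K27ac, and 57 and 379, and 324 and 62, in H3K27me3. On the X chromosome H2AK119ub1 and H3K27me3 fell further (window medians -1.16 and -1.44) than H3K4me3 (-0.40) and H3K27ac (-0.54). The offset therefore raises the active marks of X-linked promoters, 131 tested in H3K4me3 and 130 in H3K27ac. How many of the calls on this scale are X-linked was not counted. The authors chose and marked these genes by a criterion not given in the sources used here, so neither the division nor a list drawn from these genes is independent evidence of a direction.

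**Figure D1:**
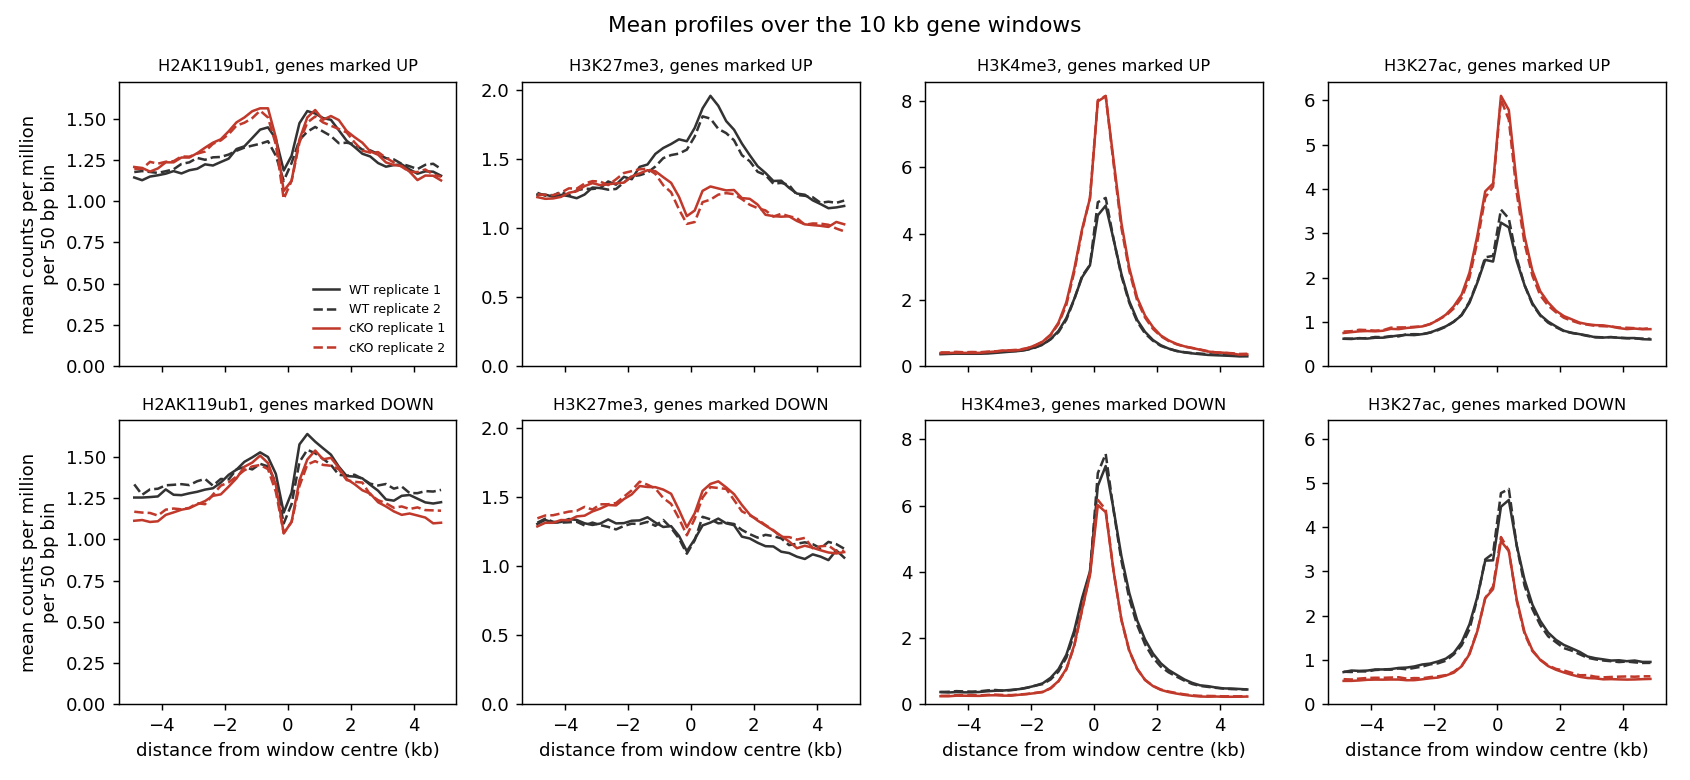
Mean CPM per 50 bp bin (y axis) against distance from the gene start in kb (x axis) for each of the 4 libraries of a mark, with genes marked UP above and genes marked DOWN below. Within 2 kb of the starts of genes marked UP, H3K4me3 was 2.10 ± 0.0148 CPM in WT and 3.23 ± 0.0335 in cKO (mean ± SD of 2 libraries), H3K27ac 1.71 ± 0.0305 and 2.69 ± 0.0695, H3K27me3 1.61 ± 0.0553 and 1.27 ± 0.0274, and H2AK119ub1 1.37 ± 0.0441 and 1.42 ± 0.0221.

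The 7 measured osteoblast genes lost H3K4me3, while 5 lost H3K27ac and 4, not all of them the same genes, gained H3K27me3. Of 28 genes on the list, 7 were among the genes measured, all of them marked DOWN: Col1a1 and Col1a2, the chains of type I collagen, Spp1, coding for osteopontin, Alpl, the bone alkaline phosphatase, Tnfrsf11b, coding for the osteoclast inhibitor osteoprotegerin, Wnt10b and Msx2. H3K4me3 fell at all 7 (camera adjusted p = 0.0215, and adjusted p = 0.773 with an estimated correlation), from -3.51 ± 0.12 at Col1a2, -3.08 ± 0.12 at Wnt10b and -2.88 ± 0.19 at Spp1 to -0.37 ± 0.09 at Col1a1. H3K27ac fell at 5, with Alpl (-0.53) and Col1a1 (-0.26) not past the test (camera adjusted p = 0.0215, and adjusted p = 0.773 with an estimated correlation). H3K27me3 rose at 4, Col1a1 (1.59 ± 0.30), Wnt10b (1.43 ± 0.28), Spp1 and Msx2 (0.80 ± 0.28), and fell at 0 (camera adjusted p = 0.0635, and adjusted p = 0.773 with an estimated correlation; 0.00798 relative to neighbouring genes, where no correlation was estimated). H2AK119ub1 rose at Col1a1 (1.12 ± 0.21) and fell at Alpl (-0.86 ± 0.23). Adjusted over the list alone, the counts were the same in H3K4me3, H3K27ac and H3K27me3, and 2 rose and 2 fell in H2AK119ub1.

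Of 81 transcription factor genes known as Polycomb targets in other cells 7 were measured, 5 of them marked UP. H3K27me3 fell at 4 of the 7, Pax8 (-2.33 ± 0.27), Gata2 (-2.02 ± 0.26), Irx1 (-1.93 ± 0.28) and Otx1 (-1.89 ± 0.29), regulators of thyroid and kidney, blood and endothelium, limb and heart, and forebrain. It rose at 0 (5 fell when adjusted over the list alone; median -1.89, camera adjusted p = 0.0273, and adjusted p = 0.773 with an estimated correlation). The same 4 genes gained H3K27ac, and with Tbx2 (0.81) they gained H3K4me3, 5 in all (6 adjusted over the list alone; camera adjusted p = 0.0635, and adjusted p = 0.773 with an estimated correlation; 0.0286 relative to neighbouring genes, with the preset correlation). H3K27ac rose at 4 and fell at Gata6 (-0.56), with 4 and 2 adjusted over the list alone (camera adjusted p = 0.252). H2AK119ub1 fell at Gata2 (-0.76 ± 0.20), Gata6 and Neurod1, 3 also adjusted over the list alone (camera adjusted p = 0.0703). Of 39 Hox genes 6 were measured, 5 of them marked DOWN. H3K4me3 fell at 4 and rose at Hoxa2 (0.77), and H3K27ac fell at 4 and rose at 0. H3K27me3 rose at Hoxc11 (1.74 ± 0.26) and Hoxc13 and fell at 0, and H2AK119ub1 passed at 0 of them. The counts were the same adjusted over the list alone (camera adjusted p from 0.172 to 0.345, and 0.0317 for H3K27me3 relative to neighbouring genes with the preset correlation; for H3K27me3 adjusted p = 0.773 with an estimated correlation). At Hoxc11 H3K4me3 changed by -2.96 ± 0.12 and H3K27ac by -2.35 ± 0.20.

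Genes of the haematopoietic niche were mixed. Of 30 on the list 13 were measured, 10 of them marked DOWN. H3K27ac fell at 8 and rose at 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.174). H3K4me3 fell at 7 and rose at 3, the same adjusted over the list alone (camera adjusted p = 0.290). The losses included Vcam1, an adhesion molecule for blood progenitors (H3K27ac -1.83 ± 0.22), Angpt1 (H3K4me3 -1.35 ± 0.09), Cxcl12, Kitl, Spp1, Il15, which sustains natural killer cells, and Ptgs2. The gains included Jag1, a Notch ligand (H3K4me3 1.22 ± 0.08, H3K27ac 1.42 ± 0.17), and Thpo (1.60 ± 0.12 and 1.61 ± 0.21). H3K27me3 fell at Jag1 (-2.56 ± 0.29), Thpo, Bmp4 and Ptn and rose at Kitl and Spp1, 4 and 2 also adjusted over the list alone (camera adjusted p = 0.614). H2AK119ub1 rose at Foxc1 and Ptgs2 and fell at Thpo, Bmp4 and Tnfsf11 (4 and 4 adjusted over the list alone; camera adjusted p = 0.877). Of 22 myeloid and inflammatory cytokine genes 5 were measured. Cxcl1, a neutrophil attractant, gained H2AK119ub1 (1.12 ± 0.22) and H3K27me3 (1.73 ± 0.29) and lost H3K4me3 (-1.08 ± 0.13) and H3K27ac (-1.90 ± 0.19). Ccl7 gained H2AK119ub1 (0.94 ± 0.22) and lost both active marks. Counts of higher and lower genes on this list were 2 and 0 in H2AK119ub1, 1 and 0 in H3K27me3, 2 and 2 in H3K4me3 and 1 and 3 in H3K27ac. Adjusted over the list alone they were 2 and 3 in H3K27ac and otherwise the same (camera adjusted p from 0.0635 to 0.877).

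Genes of other stromal lineages changed in both directions. Of 24 adipocyte genes 9 were measured. Pparg, Fabp4, a fatty acid carrier (H3K4me3 -3.88 ± 0.18), the lipid droplet gene Plin4 (-3.29 ± 0.15) and Lpl lost both active marks, while Prdm16 gained both (H3K4me3 1.55 ± 0.11, H3K27ac 2.79 ± 0.21) and Pnpla2, Cebpd and Cebpa gained H3K4me3 (0.65, 0.42 and 0.24). Counts of higher and lower genes were 4 and 4 in H3K4me3, 3 and 4 in H3K27ac, 1 and 2 in H3K27me3 and 1 and 3 in H2AK119ub1. Adjusted over the list alone they were 4 and 5, 4 and 4, 1 and 2, and 1 and 4 (camera adjusted p from 0.290 to 0.907). Of 22 chondrocyte genes 6 were measured. Sox9, Col11a1, a cartilage collagen (H3K4me3 1.47 ± 0.10, H3K27ac 1.14 ± 0.23), and Fgfr3 (1.59 ± 0.10 and 1.44 ± 0.24) gained both active marks. H3K27me3 fell at Col11a1, Fgfr3 (-1.23 ± 0.27) and Comp. The counts were 3 and 1 in H3K4me3, 4 and 0 in H3K27ac, 0 and 3 in H3K27me3 and 1 and 1 in H2AK119ub1, the last 2 and 1 adjusted over the list alone and the others the same (camera adjusted p from 0.207 to 0.907). Of 29 limb mesenchyme and stromal genes 14 were measured, 11 of them marked DOWN. Pdgfrb, a pericyte receptor (H3K4me3 -2.24 ± 0.09, H3K27ac -2.19 ± 0.16), Eng, coding for endoglin (-3.83 ± 0.19 and -1.58 ± 0.21), Ly6a, coding for the progenitor antigen Sca-1, and Shox2 lost active marks. The BMP antagonist gene Grem1 gained both (H3K4me3 1.89 ± 0.13) and its H3K27me3 fell (-2.02 ± 0.26). The counts were 3 and 7 in H3K4me3, 1 and 9 in H3K27ac, 2 and 1 in H3K27me3 and 1 and 2 in H2AK119ub1, the same adjusted over the list alone (camera adjusted p = 0.129 in H3K27ac, 0.279 in H3K4me3, and 0.907 and 0.926 in the others).

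Of 40 Wnt, BMP and Notch pathway genes 13 were measured, and H3K4me3 rose at 9 of them and fell at Sfrp1 and Fzd7. The gains included Dkk3 (2.21 ± 0.10), Nog, coding for the BMP antagonist noggin (2.69 ± 0.15), Jag2 and Fzd2. H3K27ac rose at 5 and fell at 2, and H3K27me3 fell at Nog (-1.59 ± 0.26), Sfrp1 and Wnt4 and rose at 0. H2AK119ub1 rose at Dkk3 and Fzd2 and fell at Sfrp1 and Wnt4. Adjusted over the list alone H3K27ac rose at 4 and the other counts were the same (camera adjusted p from 0.283 to 0.877). Of 42 genes of the BAP1 and Polycomb machinery 6 were measured. Ezh1, Foxk2, Kmt2c and Phf19 gained H3K4me3, and Foxk2 (1.01 ± 0.16), Kmt2c (1.10 ± 0.14) and Phf19 (1.80 ± 0.20) gained H3K27ac while Cbx7 lost it. H3K27me3 rose at Bmi1 (1.42 ± 0.29) and Ezh1 and fell at Phf19, and H2AK119ub1 rose at Ezh1 and fell at Cbx7 and Phf19. The counts were the same adjusted over the list alone (camera adjusted p from 0.290 to 0.945). Of 22 cell-cycle inhibitor and p53 genes 7 were measured. Cdkn2b, a cyclin-dependent kinase inhibitor (0.92), Mdm2 (0.91) and Ccne1 (0.77) gained H2AK119ub1, and Pmaip1 and Gadd45a lost it. Higher and lower genes numbered 0 and 0 in H3K27me3, 2 and 2 in H3K4me3 and 1 and 2 in H3K27ac, and the counts were the same adjusted over the list alone (camera adjusted p from 0.587 to 0.945). Over all 11 lists and 4 marks, 3 of 44 camera tests passed, those of the osteoblast and Polycomb-target lists above, and 0 with an estimated correlation. The other 41 had adjusted p from 0.0635 to 0.945. The median, the mean and the test differed in sign for the machinery list in H2AK119ub1 (median 0.30, mean -0.01) and H3K27me3 (0.22 and -0.14). They also differed for the Wnt list (0.11 and -0.12) and the limb list (-0.06 and 0.004) in H3K27me3, and the cell-cycle list in H3K4me3 (0.04 and -0.09) and H3K27ac (0.27 and -0.06). Relative to neighbouring genes, some genes named from the lists lost their call. In H2AK119ub1 these were Col1a1, Alpl, Gata2, Gata6, Ptgs2, Prdm16, Lpl, Sox9, Comp, Dkk3, Fzd2, Wnt4, Cbx7, Ezh1, Cdkn2b, Ccne1, Gadd45a, Tubb3 and Des. In H3K27me3 they were Sfrp1, Wnt4 and Ezh1, in H3K4me3 Alpl, Il15, Cebpa, Ezh1, Foxk2 and Tubb3, and in H3K27ac Il15, Ly6a, Sox9, Gata6, Cbx7, Cdkn2b and Tubb3.

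**Figure D2:**
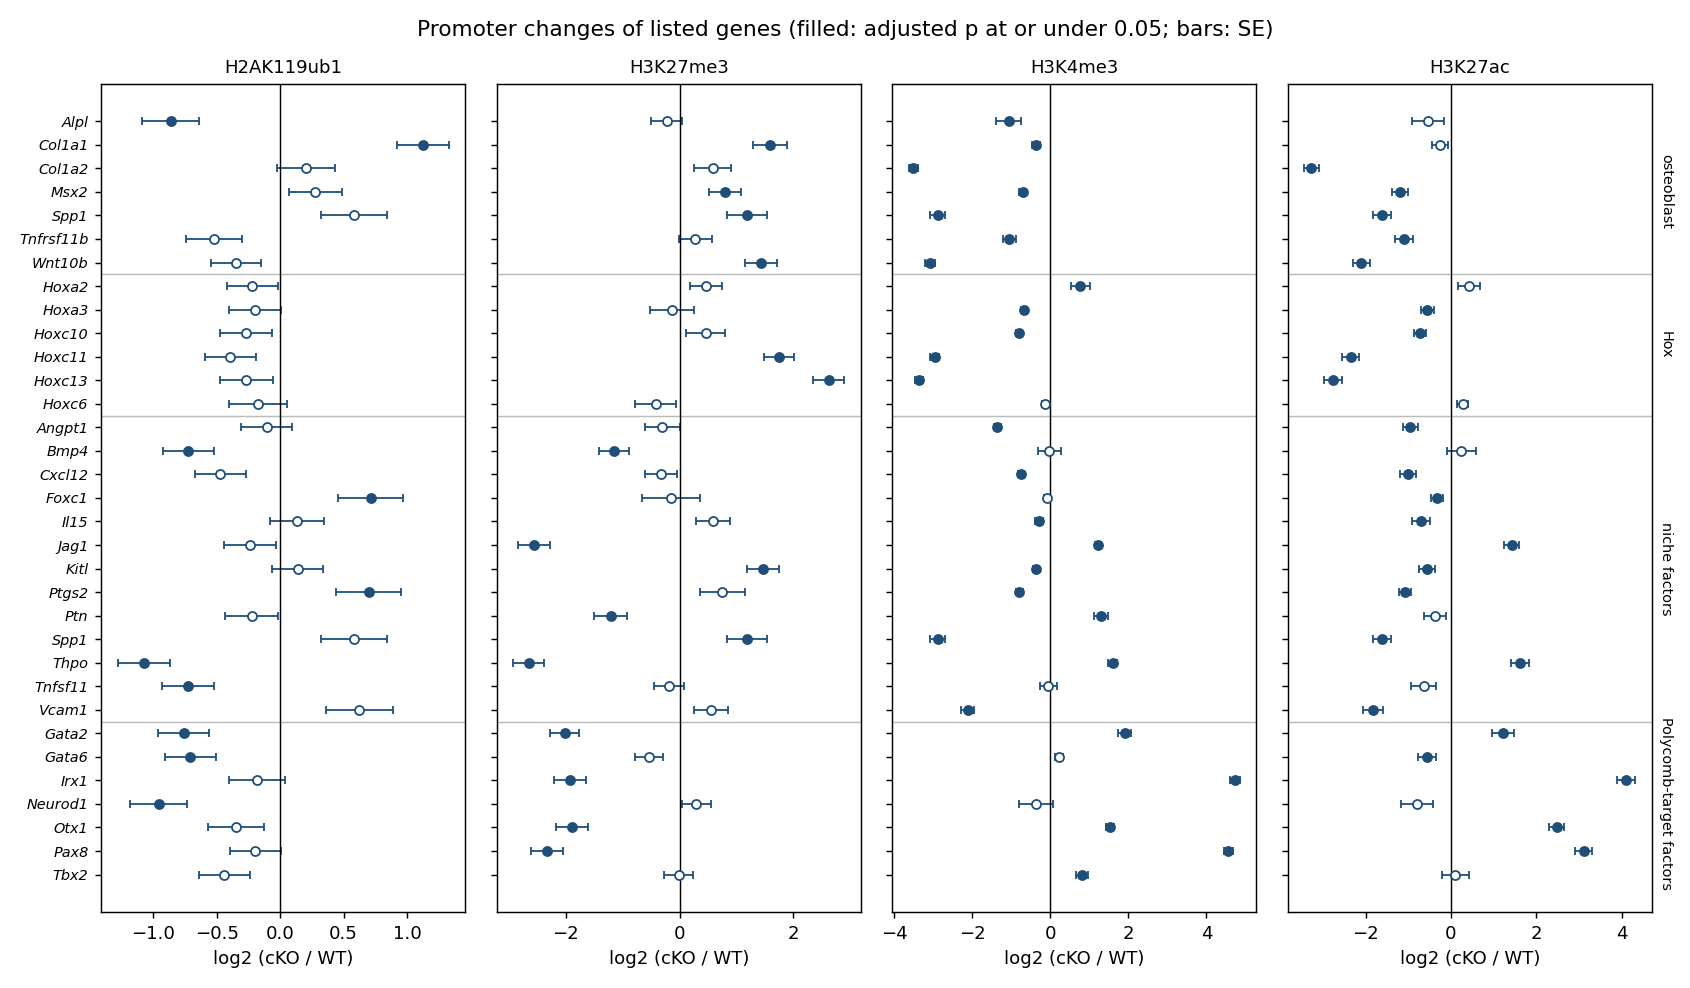
Log2 change in cKO against WT (x axis, bars show SE, 2 libraries per genotype) of each measured gene of the osteoblast, Hox, niche and Polycomb-target lists (y axis), 1 panel per mark, with filled points for an adjusted p at or under 0.05. At Col1a2 H3K4me3 and H3K27ac changed by -3.51 and -3.27 and at Pax8 by 4.56 and 3.11, where H3K27me3 changed by -2.33.

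Few markers of other cell types were among the genes measured, and these lists were too short for a set test. Of 32 haematopoietic markers 3 were present. Lcp1 lost H2AK119ub1 (-0.69) and H3K4me3 (-0.96), and Cd68 and Lyz2, macrophage genes, passed in 0 marks, with H3K4me3 at -0.17 and -0.19. The 1 measured of 18 endothelial markers, Egfl7, lost H2AK119ub1 (-1.07), H3K27me3 (-1.97) and H3K4me3 (-1.50). Of 19 muscle and neural markers 3 were present. Tubb3 lost H2AK119ub1 (-0.68), H3K4me3 (-0.55) and H3K27ac (-0.68), Des lost H2AK119ub1 (-0.72), and Tnnt3 did not pass in a mark. B2m, the 1 gene measured of 28 housekeeping genes, lost H3K4me3 (-0.72) and H3K27ac (-1.41) and gained H3K27me3 (0.92). Vmn2r29, the 1 vomeronasal receptor, had an H2AK119ub1 change of 1.21 (adjusted p = 0.0649). Lists this short say little of how many other cells the preparations held.

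A set of promoters exchanged H3K27me3 for active marks or the reverse. Of 3875 promoters tested in all 4 marks, 259 gained both active marks and lost H3K27me3, 257 of them marked UP, among them Pax8, Irx1, Gata2, Otx1, Gsc, Foxd1, Prdm16, Thpo, Jag1, Grem1, Nog, Fgfr3, Col11a1 and Phf19. Another 173, all marked DOWN, lost both active marks and gained H3K27me3, among them Pparg, Kitl, Spp1, Wnt10b, Msx2, Hoxc11, Hoxc13, Cxcl1, Shox2, Il18 and B2m. H2AK119ub1 fell at 93 and rose at 5 of the 259, and rose at 28 and fell at 11 of the 173. Relative to neighbouring genes the numbers were 283 and 182, with H2AK119ub1 lower at 40 and higher at 4 of the former and higher at 15 and lower at 6 of the latter. For H3K27me3 lower with H3K27ac higher, 276 promoters were found where independent lists would share 187, and for H3K27me3 higher with H3K27ac lower, 222 against 141.

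Across these 3875 promoters, which are not independent replicates, the log2 changes of H3K4me3 and H3K27ac went together (Spearman 0.827, Pearson 0.828), as did those of H2AK119ub1 and H3K27me3 (0.588 and 0.587). H2AK119ub1 correlated weakly with H3K4me3 (Spearman 0.245, Pearson 0.185) and H3K27ac (0.239 and 0.213), and H3K27me3 inversely with H3K4me3 (-0.106 and -0.219) and H3K27ac (-0.135 and -0.226). These are all 6 pairs, and the marks of a pair share no libraries. Among promoters above the median CPM of both marks, Spearman's rho was -0.405 and -0.366 for H3K27me3 with H3K4me3 and H3K27ac and 0.143 for H2AK119ub1 with H3K27ac. Relative to neighbouring genes, Spearman's rho became 0.328 for H2AK119ub1 and H3K27me3, -0.0651 and -0.112 for H2AK119ub1 with H3K4me3 and H3K27ac, and -0.435 and -0.510 for H3K27me3 with them. On this scale the marks of a pair do share libraries, since each offset is taken from Polycomb mark libraries. These shifts of rho can thus be in part by construction.

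At the 388 promoters in the top decile of WT H3K27me3, Pax8, Gata2, Foxd1 and Grem1 among them, H2AK119ub1 fell at 190 and rose at 4. Without cKO replicate 1 it fell at 6 of them, and without cKO replicate 2 at 33, and it rose at 0 in both. Of the 388, 383 are autosomal, with 185 lower. The median log2 change was -0.48 (-0.36 relative to neighbouring genes), from a median of 181 CPM in WT to 128 in cKO. H3K27me3 itself fell at 244 and rose at 5 of them (median -0.95), H3K4me3 rose at 279 and fell at 37 (median 1.08) and H3K27ac rose at 184 and fell at 32 (median 0.55). Of the class 72.7% were marked UP, where the H3K4me3 and H3K27ac medians were 1.49 and 0.87. In the 106 marked DOWN they were -0.14 and -0.26. In the 388 promoters of the top decile of WT H3K4me3, H2AK119ub1 had a median change of 0.01 (55 rose, 21 fell), which was 0.22 relative to neighbouring genes. In the 3102 in neither class it was 0.08 (591 rose, 425 fell) and 0.11 relative to neighbouring genes. With either cKO library alone against the WT mean, the median of the H3K27me3-rich class was -0.47. H3K27me3 libraries set the class, so their own change there includes regression to the mean, while the H2AK119ub1 libraries took no part in the choice. The top 2 deciles shared 0 promoters.

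**Figure D3:**
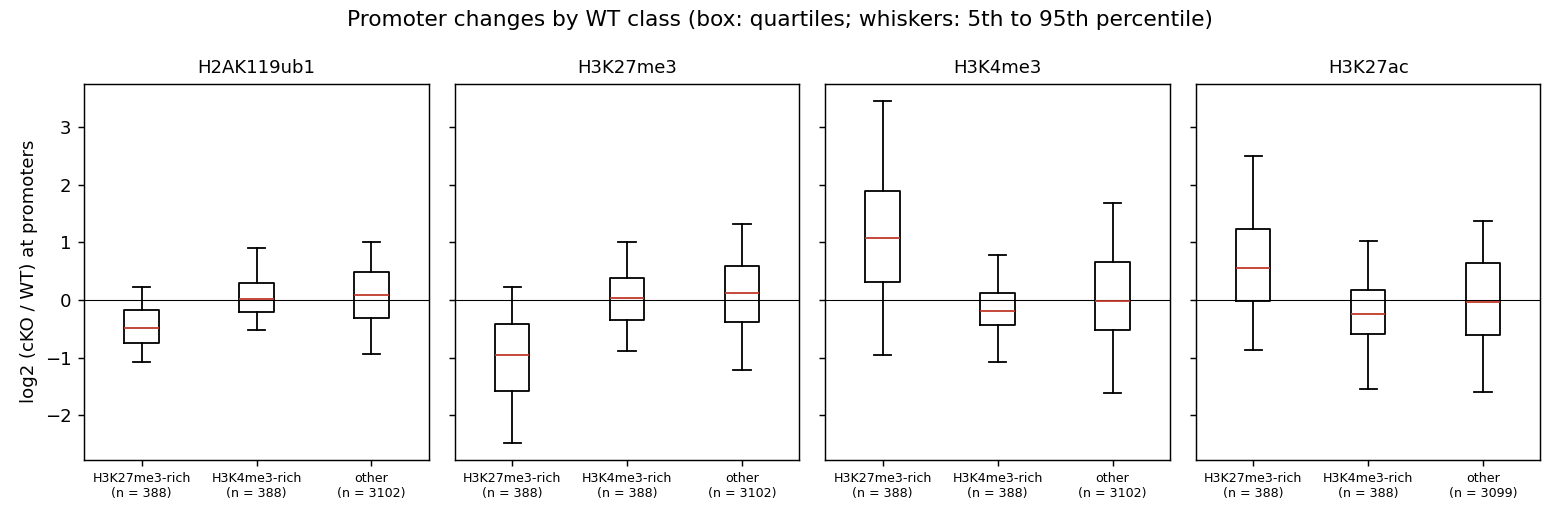
Box plots (boxes show median and quartiles) of the log2 change in cKO against WT (y axis), 1 panel per mark. Promoters are in the top decile of WT H3K27me3, the top decile of WT H3K4me3 or neither (x axis). The H3K27me3-rich class lies at -0.48 for H2AK119ub1, -0.95 for H3K27me3, 1.08 for H3K4me3 and 0.55 for H3K27ac.

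Large chromosome regions changed together, in all 4 marks. On chromosome 4 from 0 to 120 Mb, where 87.2% of 234 genes were marked UP, even the outer 1 kb flanks of the windows were higher in cKO, by a log2 of 0.59 for H2AK119ub1, 0.68 for H3K27me3, 0.66 for H3K4me3 and 0.78 for H3K27ac. From 120 to 160 Mb, with 43.8% of 89 genes marked UP, the flanks changed by -0.26, -0.39, -0.20 and -0.30. The share of genes marked UP was 75.2% on chromosome 4, 76.8% on 7, 70.0% on 11 and 68.5% on 12, but 24.6% on 1 and 25.9% on 19. Chromosome accounted for 50.4% of the variance of the H2AK119ub1 window change among autosomal genes marked UP and 29.0% among those marked DOWN (permutation p = 1e-04 for each, the smallest 10000 permutations can give). On the X chromosome H2AK119ub1 fell in 129 of 133 windows (median log2 -1.16) and H3K27me3 in 123 (median -1.44), while H3K4me3 and H3K27ac had medians of -0.40 and -0.54. The Xist promoter, of the RNA that coats the inactive X chromosome, carried 302 ± 11.6 CPM of H3K4me3 in WT and 11.8 ± 6.59 in cKO (SD, n = 2; log2 -4.60 ± 0.16, edgeR adjusted p = 9.2e-137). These regions and this gene were singled out after their values were seen.

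**Figure D4:**
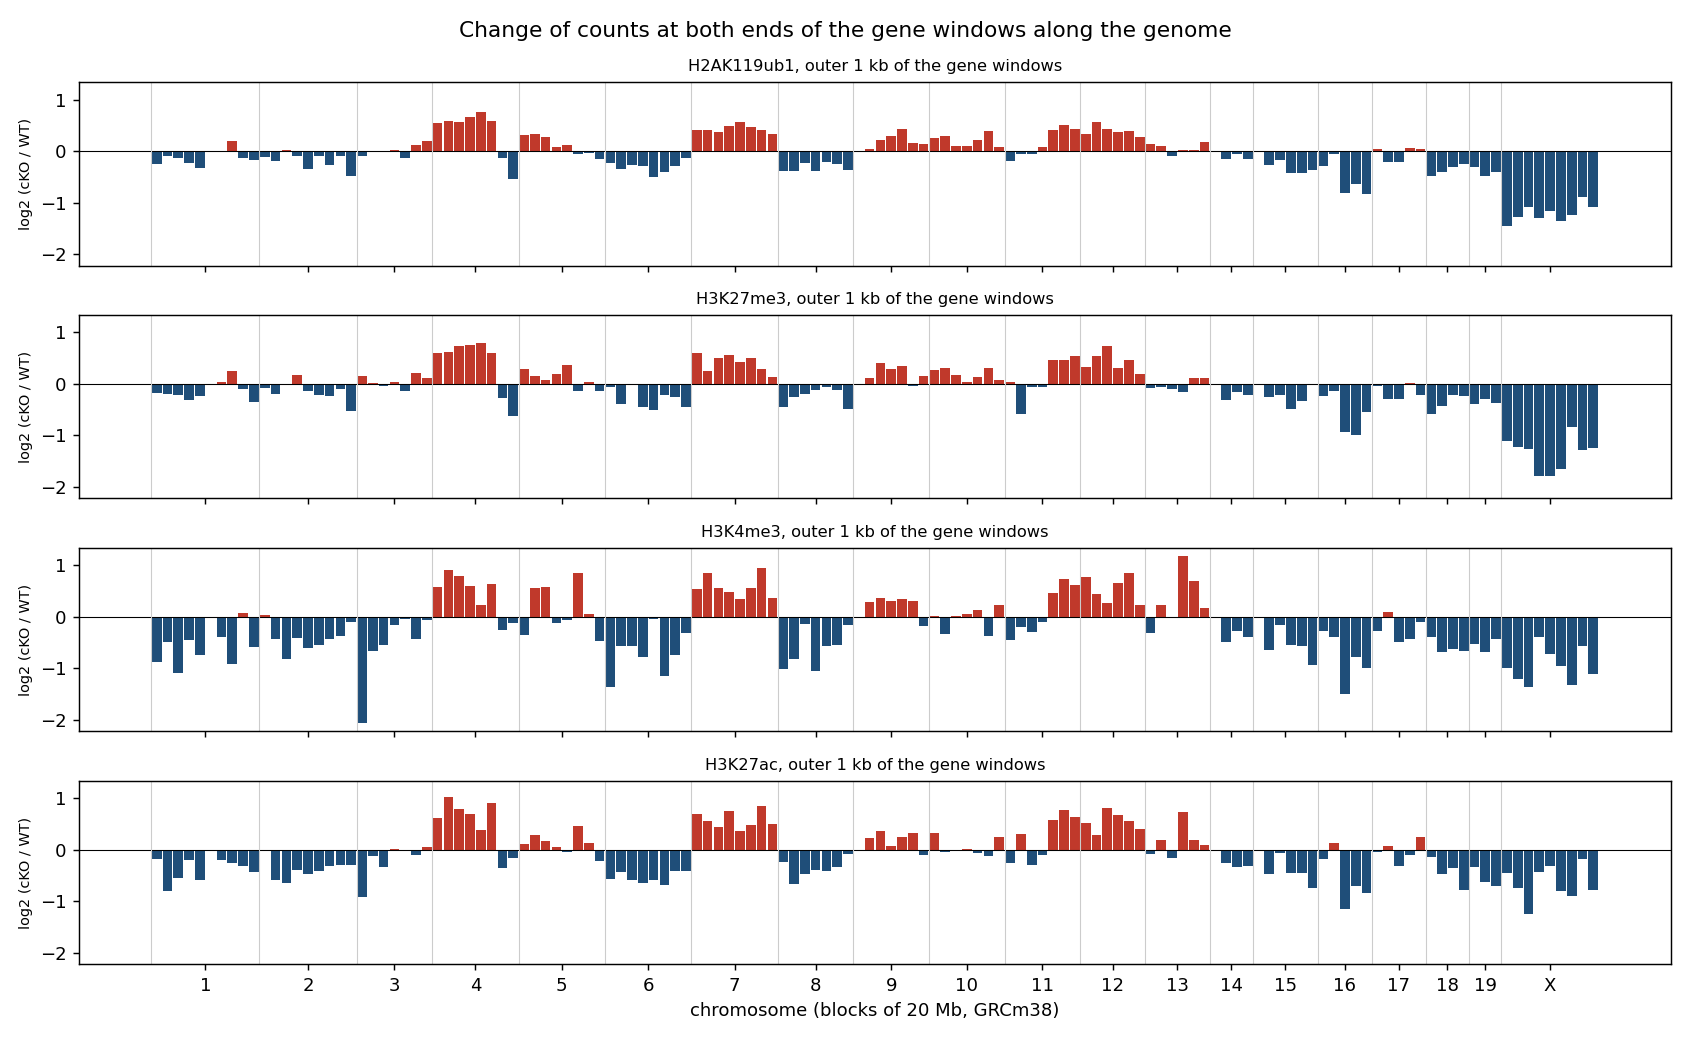
Log2 change in cKO against WT (y axis) of the outer 1 kb flanks of the gene windows, summed over 20 Mb blocks in genome order (x axis, chromosomes 1 to 19 and X), 1 panel per mark. Chromosome 4 up to 120 Mb lies above 0 in each mark (0.59 for H2AK119ub1), and the X chromosome lies below 0 (-1.21 for H2AK119ub1 and -1.38 for H3K27me3).

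In 10 kb windows over the autosomal genes, taken whole, H2AK119ub1 was higher in 860 and lower in 846 of 3771, H3K27me3 in 695 and 740 of 3774, H3K4me3 in 1473 and 1385 of 3778 and H3K27ac in 1247 and 1237 of 3772. The balance of the Polycomb marks rests on the scaling: with factors from the top 10% of windows, which move the median promoter by 0.17 for H2AK119ub1 and 0.40 for H3K27me3 on the log2 scale, the counts were 1296 and 461 for H2AK119ub1 and 1253 and 291 for H3K27me3. The directions given here are relative to the other windows measured, so a change shared by all of them would not show.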

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

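Both tests here, of whether a promoter's change differed between 2 marks (an interaction term in 1 edgeR fit of all 16 libraries, from which the log2 changes here are taken), were added to the planned comparisons.

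The change of H2AK119ub1 differed from that of H3K27me3 at 534 of 3908 promoters (BH-adjusted p at or under 0.05; 1036 at an unadjusted p under 0.05), and at 274 of these the marks had opposite signs. In 291 H2AK119ub1 lay above H3K27me3 and in 243 below. The marks differ in range. WT medians in the H3K27me3-rich class and in neither class were 181 and 102 CPM for H2AK119ub1, and 360 and 79.3 for H3K27me3. A loss of both marks down to background would thus give unlike log2 changes. This test does not tell that apart from marks changing separately. At Foxd1 the log2 changes were -0.41 for H2AK119ub1 and -3.05 for H3K27me3 (difference 2.64 ± 0.26 SE, adjusted p = 3.3e-07), and Phf19, Mn1, Jag1, Eya2 and Sema3f also lost far more H3K27me3 than H2AK119ub1, with differences from 2.29 to 2.49. At Hoxc13 the changes were -0.27 and 2.62 (difference -2.88 ± 0.31, adjusted p = 7.2e-07), at Pparg -0.37 and 1.94 (difference -2.32 ± 0.28), and Hoxc11, Impa2, Phf21b and Abcg1 likewise gained H3K27me3 without a gain of H2AK119ub1.

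The change of H3K4me3 differed from that of H3K27ac at 327 of 3908 promoters (854 at an unadjusted p under 0.05), above it in 246 and below it in 81, with opposite signs in 72. Relative to the outer 1 kb flanks, WT counts within 2 kb of gene starts were 6.66-fold for H3K4me3 and 2.77-fold for H3K27ac. The same relative change of a mark can thus move the H3K4me3 log2 value further, which was not allowed for here. Scx, the tendon transcription factor, had a log2 change of 2.08 in H3K4me3 and 0.00 in H3K27ac (difference 2.08 ± 0.27, adjusted p = 1.1e-05), Igfbp6 2.54 and 0.24, Podxl2 2.20 and -0.86, and Fbn2 4.48 and 1.89. Rbfa lost H3K4me3 (-3.86) while H3K27ac stood at -0.03 (difference -3.83 ± 0.32, adjusted p = 7.4e-09), and Eng (-3.81 and -1.58) and Plin4 (-3.29 and -1.58) lost more of the former. Akr1c14 went the other way, with 0.03 in H3K4me3 and 2.01 in H3K27ac.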

How the results depend on the processing

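The regional offset, 1 bin in 3, the flank scaling and leaving out shared windows or the X chromosome were chosen after seeing the data. Of the values of single named genes under the alternatives, 4349 kept direction and side of the threshold, 219 fell short of it, 54 passed it and 2 reversed: H3K27ac at Sesn2 and Cdkn2b became 0.063 and -0.30 relative to neighbouring genes, since the offset subtracts the regional change. Total counts, promoter TMM, DESeq2, no filter and 1 bin in 3 moved no count of called promoters by over 1.5 times. The range over left-out libraries was 4 to 564 higher and 19 to 571 lower promoters for H2AK119ub1, 268 to 447 and 358 to 625 for H3K27me3, and 753 to 1051 lower for H3K27ac; in windows it was 553 to 680 lower for H2AK119ub1 and 421 to 611 higher and 409 to 704 lower for H3K27me3. The lowest came without cKO replicate 1 for both Polycomb marks (without cKO replicate 2, 120 and 121 promoters for H2AK119ub1, 301 and 380 promoters and 425 and 462 windows for H3K27me3) and without WT replicate 1 for H3K27ac; fewer libraries were fitted, and why cKO replicate 1 matters most was not tested. Promoters of 1 kb to each side gave 267 higher and 340 lower for H2AK119ub1 and 245 higher for H3K27me3, and 5 kb gave 984 lower for H2AK119ub1. All libraries in 1 fit gave 778 higher for H3K27me3, and the regional offset 247 higher and 215 lower for H2AK119ub1. In windows, scaling on the top 10% gave 1296 higher and 461 lower for H2AK119ub1 and 1253 and 291 for H3K27me3, and 5 kb windows, of which there are more, gave 2532 and 2148 for H3K4me3 and 2044 and 1994 for H3K27ac. Across scalings the median promoter moved by over 0.1 also for H3K4me3, by -0.12 with the top 10% of windows, -0.10 with total counts and 0.15 with flanks. The median of genes marked UP minus those marked DOWN was 0.15 for H2AK119ub1 (0.15 to 0.18 over left-out libraries) and became 0.20 at 5 kb, 0.11 without shared windows and, reversed, -0.10 with the offset; for H3K27me3 it was -0.23 (-0.26 to -0.22) and became -0.29 at 1 kb, -0.11 at 5 kb, -0.50 with the offset and -0.28 without shared windows; for H3K4me3 1.07 (1.06 to 1.10) became 1.03 at 1 kb and 0.63 with the offset; for H3K27ac 1.17 (1.17 to 1.22) became 1.22, 1.08, 0.83 and 1.13. The H2AK119ub1 median of H3K27me3-rich promoters was -0.59 in the top 5%, -0.47 with total counts, -0.36 with the offset, -0.47 without the X chromosome and -0.56 to -0.41 over left-out libraries; that of H3K4me3-rich promoters was -0.058 in the top 5% and 0.22 with the offset; that of the others was 0.056, 0.10, 0.11, 0.12 and 0.065 to 0.11. Lists called went from 3 to 0 with an estimated correlation and 6 with the offset. Above the median CPM, Spearman's rho was 0.537 for H2AK119ub1 with H3K27me3, 0.211 and 0.143 with H3K4me3 and H3K27ac, -0.405 and -0.366 for H3K27me3 with them and 0.891 between them; with the offset these were 0.328, -0.0651 and -0.112 (reversed), -0.435, -0.510 and 0.775. The promoter share in cKO minus WT at 1 kb was -0.227 points for H2AK119ub1 (reversed), -1.46 for H3K27me3, 7.34 for H3K4me3 and 4.55 for H3K27ac; at 5 kb it holds all counts and is void. The causes of these shifts, other than by construction, were not tested. The replicate numbers of the titles are shared between genotypes. Within a mark, deviations of same-numbered libraries correlated at -0.0161, -0.0388, 0.0685 and 0.0507 for H2AK119ub1, H3K27me3, H3K4me3 and H3K27ac. No strong shared deviation was thus seen, but a shared day or preparation is not excluded. Libraries of different marks were not compared in this way. With the replicate number as a block, 642 promoters were higher and 623 lower for H2AK119ub1, and 453 and 568 for H3K27me3. They numbered 1592 and 1256 for H3K4me3 and 1224 and 1158 for H3K27ac. In these fits 1 named H2AK119ub1 call was lost and 3 lists were called. Depth was lowest in H3K27me3, with a median of 95 counts per promoter in WT replicate 1, and 48% of simulated 2-fold changes were recovered there.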

Other observations

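The scan of gene families and the tests of regional change and of the X chromosome were chosen after results were seen; the 4 tests of H2AK119ub1 at H3K27me3-rich promoters were set out before their values were known.

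Collagen genes as a family were not among the lists. Of 19 measured collagen genes, 14 of them marked DOWN, 12 were lower and 1 higher in H3K27ac, and 12 were lower and 5 higher in H3K4me3. H3K4me3 changed by a log2 of -4.33 ± 0.13 (SE) at Col6a3, -3.85 ± 0.16 at Col3a1, -3.51 ± 0.12 at Col1a2 and -1.82 ± 0.14 at Col8a1, while Col4a3, a basement membrane chain (2.20 ± 0.26), and Col11a1 (1.47 ± 0.10) gained it. As a set the family did not pass among 29 families of at least 8 genes sharing a symbol stem (camera adjusted p = 0.384 in both active marks, a value shared by 8 pairs of family and mark).

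Genes of ephrins, ligands of contact guidance between cells, and of their Eph receptors were singled out after their values were seen, with no set test. Of 10 measured, 5 lost H3K27me3 and gained both active marks, against 259 of all 3875 promoters, 257 of them marked UP. These were Efna1, Efna3, Efna4, Efna5 and Epha7, all marked UP, while Efnb1, Efnb2, Epha1, Epha4 and Ephb3 did not pass in all 3 marks. Genes that lie next to each other on a chromosome were counted separately, so the 5 need not be separate loci. Relative to neighbouring genes the H3K27me3 loss at Efna5 was not called. At Efna1 the log2 changes were -1.41 ± 0.29 (SE) in H3K27me3, 1.13 ± 0.10 in H3K4me3 and 1.34 ± 0.16 in H3K27ac, and H3K27ac changed by 3.06 ± 0.18 at Epha7. H2AK119ub1 fell at Efna3 (-0.98 ± 0.20) and rose at Epha7 (0.79 ± 0.23), and at Efna1, Efna4 and Efna5 it did not pass the test (-0.02, -0.36 and -0.22).

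Regional change ran along parts of chromosomes: in 121 autosomal blocks of 20 Mb the log2 change of the H2AK119ub1 flanks ran from -0.84 to 0.75. The choice of genes by UP or DOWN as its whole cause is argued against, since chromosome accounted for 29.0% of the variance of the H2AK119ub1 change among genes marked DOWN alone (permutation p = 1e-04, the smallest that 10000 permutations give). Opposed effects of the genotype on active and Polycomb marks are argued against as well, since the flanks of H3K27me3 and H3K27ac moved together over blocks (rho = 0.713). A copy number difference between the WT and cKO cells, such as cultured cells may acquire, remains a candidate explanation: H2AK119ub1 and H3K4me3 flanks moved together (rho = 0.753), as a change in DNA content would have it. A regional change of chromatin that alters the yield of all 4 precipitations stays open too, since input libraries were not used here.

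On the X chromosome the loss was uneven between marks. The H2AK119ub1 change lay below the H3K4me3 change of the same window by a median of -0.64 over 133 windows (0.03 on autosomes). Resampling these windows gave a 95% bootstrap interval of -0.81 to -0.55. Windows of 1 chromosome are not replicates, so the interval holds no spread between libraries. By cKO replicate, the X medians were -1.17 and -1.17 for H2AK119ub1 and -0.39 and -0.47 for H3K4me3. The difference argues against an even loss of X chromosome copies as the whole cause. An inactive X chromosome missing from the cKO cells, through loss or through a difference in the sex of the animals, is a candidate explanation, since the inactive copy holds much of the Polycomb marks and the Xist promoter lost nearly all H3K4me3 (log2 -4.60). Loss of the marks with both copies kept stays open, since the X flanks of H3K4me3 (-0.77) lay within 1 SD of the autosomes' median (median -0.32, SD 0.473, 19 autosomes), though below the lowest of them (-0.66). Named X-linked calls such as Jpx and Gpr173 in H2AK119ub1 carry this shift.

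H2AK119ub1 fell at 190 and rose at 4 of 388 H3K27me3-rich promoters (6 and 33 lower without cKO replicate 1 or 2), although the deleted enzyme removes this mark. Choice of the promoters by their WT level is argued against, since in the top decile by the mean over all 4 H3K27me3 libraries the median was -0.43 (175 lower and 8 higher of 388; without cKO replicate 1 or 2, 2 and 26 lower of the 387 autosomal ones), and so is the larger share of genes marked UP, since the class members marked DOWN had a median of -0.61 (63 lower and 2 higher of 106, all autosomal; without cKO replicate 1 or 2, 1 and 16 lower with medians of -0.59 and -0.53). Weaker enrichment in the cKO libraries cannot be told apart from a local loss, since 203 other promoters as rich in H2AK119ub1 had a median of -0.068, with 57 higher and 38 lower, between the values set for either outcome. A rise of the mark everywhere else hidden by scaling also cannot be told apart, because the median on the flanks' scale (-0.43) is still relative to the windows measured. A local loss at Polycomb-rich promoters on deletion of Bap1 remains a hypothesis, and no test here decides between it and the 2 left open. The labels do not say that the libraries of a group came from separate animals. Another difference between the WT and cKO cells therefore cannot be told apart from the deletion either.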
